A study of Mus musculus with 6 samples.

How the data were processed

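Poly-A RNA sequencing libraries were made from liver cells of 1-year-old p16-Cre/Rosa26-mTmG mice, enriched for CD31 on magnetic columns and sorted by GFP, per the labels' protocols. Sorting gave 3 GFP-negative and 3 GFP-positive libraries, and the group of each was taken from its label of sorted cells. The labels carry no animal, batch or shared replicate number, so replicate numbers only name libraries and no pairing was made. The labels' protocols state an input of 1 μg of total RNA per library, complementary DNA of selected fragment length, and PCR without molecular identifiers.

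The authors deposited 1 table of raw counts per gene for all 6 libraries, with 35275 Ensembl gene identifiers and whole numbers that sum to a different total in each library. Of these identifiers 34490 were matched to a gene symbol in a supplied table of gene names and 785 were not, and 16436 had 0 counts in every library. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1, RSEM, DESeq 1.18.0 and edgeR, without saying what each was used for. The genome build, the gene annotation, and whether reads were counted by strand are not given in the sources used here, so no coordinates are printed, and reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies, such as immunoglobulin segments, haemoglobin genes, the Ear, Pira and Ly6c families, C4b, and Hspa1a and Hspa1b, are uncertain, because the counting could divide or drop their shared reads.

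Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filter on low expression with its minimum count of 10, which left 12122. Library sizes were scaled by TMM, dispersions were estimated robustly, and the GFP-positive group was compared with the GFP-negative group by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05, with no threshold on the fold change. Log2 fold changes are GFP-positive minus GFP-negative, and their standard errors were derived from the test statistic. CPM are counts scaled by the TMM library sizes. The common biological coefficient of variation was 0.816.

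The totals of 16766556 to 22627555 counts put the floor of 3 counts over a group at 0.0496 CPM for the GFP-negative and 0.0584 CPM for the GFP-positive group. Where all libraries of a group held 0 counts, the fold was computed against that floor and is a lower bound. Where a group held 1 to 3 counts, the ratio is given with its exact 95% counting interval. Both cover counting error in the low group only. They take the mean of the other group as fixed and leave out the spread between libraries. Fitted fold changes of such genes depend on a prior count. The median of each list was the same with such genes set at their bound.

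Before the data were examined, 31 lists of 461 symbols in all were fixed, of which 2 symbols had no identifier in the table. They hold cell-cycle inhibitors, senescence-associated secretory genes, proliferation genes, markers of sinusoidal, pan-, central vein, arterial and lymphatic endothelium, and markers of Kupffer cells, macrophages and monocytes, dendritic cells, neutrophils, B cells, T and NK cells, platelets, erythroid cells, hepatocytes, stellate cells and fibroblasts, and cholangiocytes. The others hold scavenger receptors, lysosomal, antioxidant, extracellular matrix, lipid handling, interferon response, antigen presentation, immediate-early, mitochondrially encoded and ribosomal protein genes, and genes of Notch signalling and of endothelial-mesenchymal transition. For each list the members higher, lower and not past the test were counted over all genes tested and with p-values adjusted over the list alone. Lists were compared with all other genes by limma's camera on voom values. This used its preset correlation of 0.01 and a correlation estimated from the data, each adjusted over the 31 lists. A camera adjusted p printed without a named correlation is that with the preset one. Lists were also tested by fry, adjusted likewise, which asks whether a list changed and not whether it differs from other genes. After the data had been seen, 6 lists were added, of early-response genes that lymphocytes hardly use, Kupffer cell transcription factors, iron handling, complement, naive B cell and germinal centre, and plasma cell genes, and these were adjusted over the 6.

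The genes to be named were also fixed by rule before the data were examined. They were Cdkn2a and Pecam1 in any case. Next came the 10 genes with the largest log2 fold change in each direction among those past the test, with a mean log2 CPM of at least 2, no overlap between the groups and a proper gene name. From each list came up to 4 members with the smallest p, those moving with most of the list first, any member called against the list, and for markers of other cell types also the 2 most abundant. This gave 159 genes beside Cdkn2a. The text describes part of them. Results of the others are not reported here, although all count in the totals and in the lists. Cdkn2a was removed by the filter, so it was compared by a two-sided exact permutation test on log2(CPM + 1) and by edgeR without the filter.

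The edgeR analysis was tested on simulated data of the same 12122 genes, with 50 genes changed at each of 4 sizes. It recovered 4% of genes changed 2-fold, 26% changed 4-fold, 38% changed 8-fold and 50% changed 16-fold, none with the wrong sign, and 6 of its 65 calls were false. Most 2-fold changes were out of reach in this simulation. It drew its changed genes from a middle range of mean counts, so the rates do not cover weaker or stronger genes. It changed far fewer genes than passed in the comparison itself, which makes the adjusted threshold stricter, so these rates may not hold there.

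The alternatives were DESeq2's Wald test, limma-voom with and without sample quality weights, DESeq2's size factors, upper-quartile scaling, library totals alone, no filter, a filter of at least 50 counts in at least 3 libraries, an absolute log2 fold change of at least 1, an adjusted p under 0.01, leaving out hepatocyte, erythroid and mitochondrial genes, and leaving out each library in turn. Leaving out immunoglobulin, B, T and NK cell genes, and the filters for the similarity of replicates, were added after the data had been seen. Reporter transcripts were not analysed here.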

Results

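Gene expression was measured by poly-A RNA sequencing in cells of the mouse liver that carry CD31. CD31, the product of Pecam1, is an adhesion molecule of endothelial cells that platelets and many leukocytes also carry. The mice were 1 year old and held a Cre recombinase driven by the p16 gene together with a membrane reporter that Cre switches from a red protein to GFP. A cell thus turns green when it or a cell it descends from has used the p16 promoter. CD31-positive cells were enriched with magnetic beads. They were then sorted by flow cytometry into a GFP-positive and a GFP-negative fraction, with 3 libraries of each. The growth protocol also describes culture of the enriched cells in endothelial medium, and it is not given in the sources used here whether these libraries were made before or after such a culture. The libraries held between 16766556 and 22627555 counts. The GFP-negative libraries 1 to 3 held 19332784, 18067411 and 22627555 counts over 15359, 14868 and 14819 genes, and the GFP-positive libraries 1 to 3 held 16766556, 17306500 and 17849620 counts over 13369, 13036 and 13012 genes. The labels name no animal or batch, so the p-values below measure the spread between these libraries, which may be technical.

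Across genes, Spearman's correlation between libraries was 0.901 to 0.906 within the GFP-negative group, 0.866 to 0.872 within the GFP-positive group and 0.700 to 0.729 between the groups. Every pair of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 73.7 to 125.5, so no pair was counted as 1 library deposited under 2 labels. Separate libraries made from the same RNA would exceed that noise too, so this does not show separate animals. The leading principal component held 51.9% of the variance and parted the groups. The next held 16.2% and set GFP-positive library 2, at −136.7, apart from GFP-positive libraries 1 and 3, at 61.3 and 89.8.

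Transcripts of Cdkn2a (ENSMUSG00000044303), the gene whose promoter drives the Cre, were detected in each GFP-positive library and in no GFP-negative library. The gene encodes p16 and also the tumour suppressor Arf, which gene-level counts cannot tell apart. The 3 GFP-positive libraries held 15, 27 and 7 counts, a mean of 0.963 ± 0.593 in counts scaled by library size (CPM; SD, n = 3), and the 3 GFP-negative libraries held 0 counts each. Set against 3 counts over the whole GFP-negative group, this is at least 19.4-fold higher. A two-sided exact permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow. The gene was too low for the filter on low counts, and without that filter edgeR gave an adjusted p of 0.157 over 18839 genes. Intervals and floors from counts cover counting error only, because reads without molecular identifiers are not independent molecules.

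The comparison of the GFP-positive with the GFP-negative fraction asks which cells and genes set liver CD31-positive cells with a history of p16 promoter use apart from those without. GFP-positive libraries held more transcripts of Kupffer cells, the resident macrophages of the liver, more transcripts of liver endothelium, and more of scavenger receptors and lysosomal enzymes. They held far fewer transcripts of B cells and of immediate-early genes. Vsig4, a complement receptor of Kupffer cells, stood at 1647 ± 122 CPM in GFP-positive and 74.0 ± 1.28 CPM in GFP-negative libraries (mean ± SD, n = 3 each), a log2 fold change of 4.48 ± 0.12 (SE; edgeR adjusted p = 9.1e-06). Cd79a, a signalling chain of the B cell receptor, stood at 21.6 ± 13.5 against 2845 ± 180 CPM, a log2 fold change of −7.04 ± 0.55 (edgeR adjusted p = 0.000359).

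Of 12122 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2157 (17.8%) passed an adjusted p of 0.05, 927 higher and 1230 lower in GFP-positive libraries. Of these, 1891 had an absolute log2 fold change of at least 1, and 437 had 3 or fewer counts over all libraries of 1 group. Leaving out GFP-negative library 1, 2 or 3 left 920, 968 or 961 genes, and leaving out GFP-positive library 1, 2 or 3 left 1494, 1407 or 1603. Immunoglobulin genes took 1.57 ± 0.129% of all counts in GFP-negative and 0.0167 ± 0.00388% in GFP-positive libraries (mean ± SD, n = 3). With these and the B, T and NK cell marker genes left out, an alternative added after the data had been seen, 1695 genes passed, 713 higher and 982 lower.

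Among the 841 genes eligible to be named as higher, the 10 with the largest log2 fold changes were Ear2, Pira2, Slc16a9, Cd300a, Fcgr1, Trpm2, Clec4a3, Il1b, Vsig4 and Chp2. Pira2, an activating receptor of myeloid cells, rose by a log2 fold change of 5.43 ± 0.74 (SE; adjusted p = 0.00401), and Cd300a, an inhibitory receptor of myeloid cells, by 4.86 ± 0.41 (adjusted p = 0.000490). Ear2, a ribonuclease of myeloid cells, rose by 5.70 ± 1.11 (adjusted p = 0.0159). But without GFP-negative library 3 its adjusted p was 0.0718, and without GFP-negative library 1 its log2 fold change was 6.78. Other calls were also lost without 1 library: Chp2 and Trpm2 without GFP-negative library 2 (adjusted p = 0.0841 and 0.0954), and Trpm2 without GFP-positive library 3 (0.0655). Il1b lost its call without GFP-negative library 2 (0.108) or any 1 GFP-positive library (0.0598 to 0.0780). Slc16a9 lost its call without GFP-negative library 1 (0.104) or any 1 GFP-positive library (0.0516 to 0.0786), and Fcgr1 in every such fit except that without GFP-negative library 2 (0.0665 to 0.109). Without GFP-negative library 3 the log2 fold changes of Slc16a9, Fcgr1 and Chp2 were 6.98, 5.60 and 5.58, against 5.29, 4.79 and 4.46 with all libraries. Without GFP-negative library 1 those of Trpm2 and Clec4a3 were 5.98 and 5.38, against 4.76 and 4.59. Ear2 and Pira2 belong to families of similar genes that share reads, so their values are uncertain.

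Among the 768 genes eligible to be named as lower, those with the largest log2 fold changes included Siglecg, Ikzf3, Igkv1-135, Cr2, P2ry10, Igkv10-96, Sorl1, Dtx1 and Gpr183. Siglecg, an inhibitory receptor of B cells, had 0 counts in GFP-positive libraries against 193 ± 30.6 CPM in GFP-negative ones, which is at least 3301-fold lower. Ikzf3, a transcription factor of lymphocytes, held 2 counts over the GFP-positive group and a GFP-negative to GFP-positive ratio of 4693 (95% counting interval 1299 to 38755). Igkv1-135 also held 2 counts and a ratio of 2867 (794 to 23672). The other 6 named here fell by log2 fold changes from −11.24 (Cr2) to −8.88 (Gpr183). Without GFP-positive library 2 those of P2ry10, Igkv10-96 and Gpr183 were −11.19, −12.15 and −12.11, against −10.48, −9.98 and −8.88. Without GFP-positive library 1 those of Sorl1 and Ikzf3 were −10.59 and −14.77, against −9.65 and −11.96. Igkv segments share reads with near-identical segments, so the 2 named here are uncertain.

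**Figure D1:**
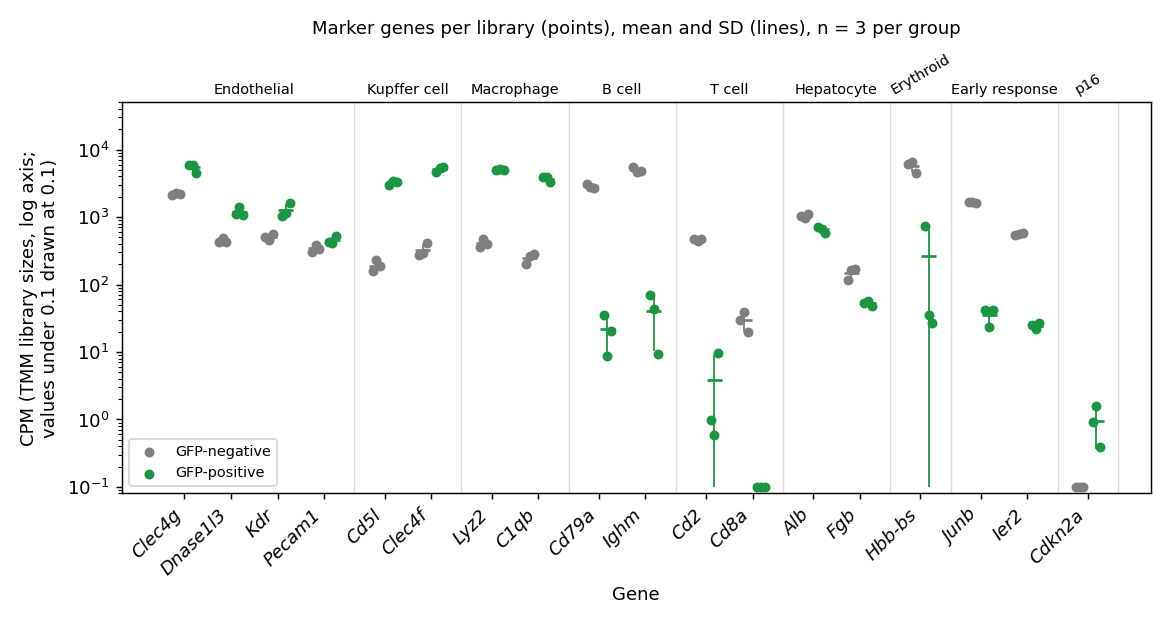
CPM of marker genes (log axis; values under 0.1, and SD lines reaching below it, are drawn at 0.1) in the 3 GFP-negative (grey) and 3 GFP-positive (green) libraries, with each library as a point and the mean and SD as lines. The Kupffer cell and macrophage genes shown lie higher and Cd79a, Ighm, Cd2, Cd8a, Junb and Ier2 lower in GFP-positive libraries, for example Lyz2 at 5019 against 413 CPM and Ier2 at 24.5 against 558 CPM.

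Kupffer cell markers rose together. All 9 measured members were higher over all genes tested, and all 9 adjusted over the list alone, with a median log2 fold change of 3.999 (camera adjusted p = 0.0224 with an estimated correlation). Clec4f, a lectin of Kupffer cells, stood at 5212 ± 464 against 326 ± 78.3 CPM (mean ± SD, n = 3 each), a log2 fold change of 3.999 ± 0.19 (SE; edgeR adjusted p = 5.2e-05). Cd5l, a secreted macrophage protein, rose by 4.08 ± 0.16 (adjusted p = 2.5e-05), and Slc40a1, the iron exporter ferroportin, by 2.89 ± 0.11 (adjusted p = 1.8e-05). Among 17 measured macrophage and monocyte markers 13 were higher, 1 was lower and 3 did not pass, against 14 higher and 1 lower adjusted over the list alone, with a median of 3.47 (camera adjusted p = 0.0218 with an estimated correlation). Lyz2, lysozyme, rose by 3.60 ± 0.12 (adjusted p = 1.5e-05) and C1qb, a chain of complement C1q, by 3.87 ± 0.16 (adjusted p = 3.3e-05). The lower member was Ly6c2, a marker of inflammatory monocytes, at −6.50 ± 1.62 (adjusted p = 0.0338). This call was lost in every fit that left out 1 library except that without GFP-positive library 1 (up to 0.135 without GFP-negative library 1, where its log2 fold change was −5.80). Of the 9 Kupffer cell markers 4 are also in other lists. Pan-endothelial markers were higher in the same libraries by a smaller amount, with a median of 1.09, and B cell markers lower, with a median of −6.93.

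Endothelial genes were higher in GFP-positive libraries, by about 1 on the log2 scale. B cell markers were lower in the same libraries, with a median of −6.93. A lower share of lymphocyte RNA would raise endothelial markers too, and it was not tested apart from other causes. Of 18 measured markers of liver sinusoidal endothelium, the fenestrated lining of the hepatic sinusoids, 14 were higher, 0 lower and 4 not past the test, and all 18 were higher adjusted over the list alone (median 1.33; camera adjusted p = 0.0238 with an estimated correlation). Clec4g, a lectin of sinusoidal endothelium, stood at 5443 ± 814 against 2178 ± 70.1 CPM (mean ± SD, n = 3 each), a log2 fold change of 1.32 ± 0.12 (SE; edgeR adjusted p = 0.000691). Gpr182, a receptor of endothelium, rose by 1.34 ± 0.11 (adjusted p = 0.000337). Of 20 pan-endothelial markers 11 were higher and 9 not past the test, against 19 higher adjusted over the list alone (median 1.09; camera adjusted p = 0.0218 with an estimated correlation). Without GFP-negative library 1, 2 or 3, 7, 7 or 6 of them were higher. Kdr, the main receptor for vascular endothelial growth factor, rose by 1.31 ± 0.19 (adjusted p = 0.00498). Pecam1, which encodes the CD31 used to enrich the cells, stood at 453 ± 58.5 against 342 ± 41.0 CPM, a log2 fold change of 0.40 ± 0.15 that did not pass (adjusted p = 0.123). Of 10 arterial and continuous endothelial markers 5 were higher and 5 not past the test, against 8 higher adjusted over the list alone (median 1.53; camera adjusted p = 0.0242 with an estimated correlation). Without GFP-negative library 1, 3 of 13 measured members were higher, and without GFP-positive library 2, 3 of 11. Ntn4 was at 1.75 ± 0.16 (adjusted p = 0.000664) and Ltbp4 at 1.58 ± 0.22 (adjusted p = 0.00423).

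Of 7 central vein endothelial markers 2 were higher, Wnt2 and Kit, with 2 adjusted over the list alone (median 0.63; camera adjusted p = 0.169 with a preset correlation and 0.311 with an estimated correlation). Wnt2, a ligand from the endothelium around the central vein, had a log2 fold change of 0.57 ± 0.14 (SE; edgeR adjusted p = 0.0344) and Kit one of 2.24 ± 0.57 (adjusted p = 0.0366). Wnt2 lost its call whichever library was left out (up to 0.102 without GFP-negative library 1), and Kit in each such fit except that without GFP-positive library 1 (up to 0.120). Of 4 lymphatic markers 1 was lower, against 1 higher and 1 lower adjusted over the list alone (median −1.80; camera adjusted p = 0.751). The lower member was Thy1, which T cells also carry, with 1 count over the GFP-positive group and a GFP-negative to GFP-positive ratio of 185 (95% counting interval 33.2 to 7311). Its call was lost whichever library was left out (up to 0.0984 without GFP-positive library 2), and its fitted log2 fold change was −7.08, or −9.11 without GFP-positive library 1. Over the 5 members then measured, the median of the lymphatic list was −0.90 without GFP-negative library 2 and −0.65 without GFP-positive library 2. In all the endothelial lists, the Kupffer cell markers of the same libraries were higher, with a median of 3.999, and the B cell markers lower, with a median of −6.93. The mean of the sinusoidal markers less that of the pan-endothelial markers was higher in GFP-positive libraries by 0.21 ± 0.0840 (log2 scale, SE, n = 3 each). Of the 18 sinusoidal markers 5 are also in other lists, and whether Kupffer cell RNA adds to this difference was not tested.

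B cell transcripts were far lower in GFP-positive libraries. All 9 B cell markers were lower, over all genes and adjusted over the list alone, with a median log2 fold change of −6.93 (camera adjusted p = 0.0224 with an estimated correlation). Cd79a, named above, stood at 21.6 ± 13.5 against 2845 ± 180 CPM (mean ± SD, n = 3 each), a log2 fold change of −7.04 ± 0.55 (SE; edgeR adjusted p = 0.000359). Ighm, the immunoglobulin mu heavy chain, fell by 6.93 ± 0.76 on the log2 scale (adjusted p = 0.00165), with a log2 fold change of −7.56 without GFP-positive library 1. Of 10 T and NK cell markers 2 were lower and 8 not past the test, against 5 lower adjusted over the list alone (median −3.98; camera adjusted p = 0.132 with an estimated correlation). Without GFP-positive library 1, 2 or 3, 5, 3 or 4 members were lower over all genes, and without library 1 the median was −5.71. Cd8a, a co-receptor of cytotoxic T cells, had 0 counts in GFP-positive libraries against 29.3 ± 9.54 CPM in GFP-negative ones, which is at least 501-fold lower. Cd2, an adhesion molecule of T and NK cells that mouse B cells also carry, fell by 6.90 ± 1.09 (adjusted p = 0.00730), with a log2 fold change of −9.18 without GFP-positive library 3. Genes of antigen presentation were lower in 8 of 12 measured members and not past the test in 4, against 1 higher and 9 lower adjusted over the list alone (median −1.25; camera adjusted p = 0.0628 with an estimated correlation, 0.0496 with library totals alone). Cd74, the invariant chain of MHC class II, stood at 6653 ± 217 against 30207 ± 375 CPM, a log2 fold change of −2.18 ± 0.05 (adjusted p = 9.1e-06). H2-Ab1, a class II chain, fell by 1.53 ± 0.09 (adjusted p = 0.000118).

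Immediate-early and heat-shock genes, which cells switch on within minutes of dissociation or other stress, were lower in GFP-positive libraries. Of 18 measured members 16 were lower, 0 higher and 2 not past the test, with 16 lower adjusted over the list alone (median −4.01; camera adjusted p = 0.0224 with an estimated correlation). Junb, a subunit of the transcription factor AP-1, stood at 35.9 ± 10.6 against 1657 ± 25.8 CPM (mean ± SD, n = 3 each), a log2 fold change of −5.53 ± 0.26 (SE; edgeR adjusted p = 5.1e-05). Ier2, an early-response gene, fell by 4.51 ± 0.16 and Jund, another AP-1 subunit, by 4.27 ± 0.15 (adjusted p = 1.5e-05 for both). Hspa1b, an inducible HSP70, fell by 4.02 ± 0.14 (adjusted p = 1.5e-05), a value that is uncertain because its near-identical copy Hspa1a shares its reads. B cell markers fell in the same libraries, with a median of −6.93.

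Receptors and enzymes of uptake and degradation were higher in GFP-positive libraries. Of 21 scavenger and endocytic receptors 18 were higher and 3 not past the test, with 18 higher adjusted over the list alone (median 2.23, or 2.82 without GFP-negative library 1; camera adjusted p = 0.0218 with an estimated correlation). Of these 21, 13 are also in other lists, most of them markers of Kupffer cells or sinusoidal endothelium. Fcgr3, a low-affinity receptor for IgG, rose by a log2 fold change of 3.83 ± 0.16 (SE, n = 3 each; edgeR adjusted p = 2.5e-05), and Timd4, a receptor for phosphatidylserine on dying cells, by 4.24 ± 0.22 (adjusted p = 5.9e-05). Of 24 lysosomal genes 12 were higher, 1 lower and 11 not past the test, against 13 higher and 1 lower adjusted over the list alone (median 0.88; camera adjusted p = 0.0224 with an estimated correlation). Ctsb, cathepsin B, stood at 6613 ± 623 against 1093 ± 201 CPM, a log2 fold change of 2.60 ± 0.15 (adjusted p = 0.000125). The lower member was Tfeb, a transcription factor of lysosomal genes, at −2.93 ± 0.41 (adjusted p = 0.00447), and 2 were lower without GFP-positive library 2. Kupffer cell markers, with a median of 3.999, were higher in the same libraries by more than the lysosomal genes.

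Genes of oxidant defence, lipid handling and the interferon response were also higher. Of 16 antioxidant and detoxification genes 8 were higher and 8 not past the test, against 10 higher adjusted over the list alone (median 0.65; camera adjusted p = 0.0420 with an estimated correlation). Without any 1 GFP-negative library or GFP-positive library 1, 5 were higher. Hmox1, haem oxygenase 1, rose by a log2 fold change of 2.59 ± 0.31 (SE, n = 3 each; edgeR adjusted p = 0.00244) and Gpx1, a glutathione peroxidase, by 1.499 ± 0.16 (adjusted p = 0.00149). Of 15 lipid handling genes 7 were higher, 1 lower and 7 not past the test, with 7 higher and 1 lower adjusted over the list alone (median 1.12; camera adjusted p = 0.0494 with an estimated correlation). Apoe, apolipoprotein E, stood at 10147 ± 161 against 3037 ± 198 CPM, a log2 fold change of 1.74 ± 0.07 (adjusted p = 2.5e-05). Cd36, a fatty acid and scavenger receptor, rose by 2.23 ± 0.21 (adjusted p = 0.000863). With an estimated correlation, the adjusted p of the lipid list was 0.0525 with DESeq2's size factors and 0.0507 without immunoglobulin, B, T and NK cell genes, and 0.0595 to 0.109 with any 1 library left out. Of 14 interferon response genes 6 were higher and 8 not past the test, against 8 higher adjusted over the list alone (median 1.26; camera adjusted p = 0.0242 with an estimated correlation). Irf7 was at 2.13 ± 0.27 (adjusted p = 0.00285) and Bst2 at 1.22 ± 0.21 (adjusted p = 0.01001). Kupffer cell markers, with a median of 3.999, and pan-endothelial markers, with a median of 1.09, were higher in the same libraries.

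Platelet and mesenchymal genes were higher in part. Of 7 platelet markers 3 were higher and 4 not past the test, against 4 higher adjusted over the list alone (median 1.23; camera adjusted p = 0.0450 with an estimated correlation). Ppbp, a platelet chemokine precursor, stood at 818 ± 41.0 against 272 ± 30.4 CPM (mean ± SD, n = 3 each), a log2 fold change of 1.59 ± 0.13 (SE; edgeR adjusted p = 0.000355). Pf4, platelet factor 4, rose by 1.93 ± 0.27 (adjusted p = 0.00447). The mean of the platelet markers less that of the pan-endothelial markers differed by 0.51 ± 0.387 on the log2 scale (SE, n = 3 each) and overlapped between the groups, so a rise beyond that of endothelial genes is not shown. The call of Gp9, at 1.66 ± 0.31, was lost without GFP-negative library 1 or 2 (up to 0.0602 without library 2). Of 9 stellate cell and fibroblast markers 3 were higher and 6 not past the test, against 4 higher adjusted over the list alone (median 2.02; camera adjusted p = 0.0548 with an estimated correlation). Rgs5, a regulator of G protein signalling in pericytes, had a log2 fold change of 2.50 ± 0.36 (adjusted p = 0.00456). The other called members were Ecm1, lost without GFP-negative library 1 or 2 (up to 0.0796 without library 2), and Colec11. Colec11 was lost without GFP-negative library 1 or 2 or GFP-positive library 1 or 2 (up to 0.102 without GFP-negative library 2). Of 12 extracellular matrix genes 3 were higher and 9 not past the test, against 5 higher adjusted over the list alone (median 1.46; camera adjusted p = 0.118 with an estimated correlation). Without GFP-positive library 3, 1 of 13 measured members was lower. Sparc, a matrix glycoprotein of endothelium, rose by 1.46 ± 0.11 (adjusted p = 0.000305). Hspg2 lost its call whichever library was left out (up to 0.0991 without GFP-negative library 3) and Col4a1 in every such fit except that without GFP-positive library 1 (up to 0.151 without GFP-negative library 2) and with library totals alone (0.0530). Pan-endothelial markers, with a median of 1.09, were higher in the same libraries.

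Some hepatocyte transcripts were lower in GFP-positive libraries, and red cell transcripts varied between the libraries of that group. Of 16 hepatocyte markers 5 were lower and 11 not past the test, against 6 lower adjusted over the list alone (median −0.77; camera adjusted p = 0.311 with an estimated correlation). Fgb, the fibrinogen beta chain, had a log2 fold change of −1.50 ± 0.22 (SE, n = 3 each; edgeR adjusted p = 0.00555). Alb, albumin, stood at 654 ± 71.3 against 1031 ± 57.6 CPM, a log2 fold change of −0.66 ± 0.12 (adjusted p = 0.0115, and 0.0520 without GFP-negative library 3). The calls of the other 3 were also lost without 1 library: Cyp2e1 without GFP-negative library 2 or 3 or GFP-positive library 1 (up to 0.0750), Cyp3a11 in every fit except that without GFP-positive library 1 (up to 0.116), and Apoa1 in every fit except that without GFP-positive library 3 (up to 0.130). Of 6 erythroid markers 0 passed over all genes and 6 were lower adjusted over the list alone (median −4.22). The camera adjusted p was 0.000691 with a preset correlation and 0.226 with an estimated correlation. All 6 had an unadjusted edgeR p under 0.05, and 5 passed with DESeq2. Without GFP-positive library 1, 5 of 7 measured members were lower over all genes, with a median of −7.52 (camera adjusted p = 0.167 with an estimated correlation). There Hbb-bs, a beta-globin gene, was at −7.52 (adjusted p = 0.000177) and Alas2, an enzyme of haem synthesis in red cell precursors, at −11.37 (0.000219), against −4.41 and −4.89 with all libraries (0.0636 and 0.120). Haemoglobin genes share reads with near-identical copies, so Hbb-bs is uncertain. Haemoglobin genes took 0.903 ± 0.161% of counts in GFP-negative and 0.0510 ± 0.0774% in GFP-positive libraries, of which GFP-positive library 1 held 0.140%.

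Of the markers of dendritic cells, neutrophils and cholangiocytes, 1 gene passed the test. Of 6 dendritic cell and 4 neutrophil markers 0 passed with edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and 0 passed with DESeq2. Their medians were 0.076 and −0.14 and change sign under other filters or without 1 library (camera adjusted p = 0.728 and 0.971). Without GFP-negative library 3, 1 of 6 measured neutrophil markers was higher. Of 4 cholangiocyte markers 1 was lower, also adjusted over the list alone (median −1.68; camera adjusted p = 0.192). It was Epcam, an epithelial adhesion molecule, with 0 counts in GFP-positive libraries against 6.27 ± 2.42 CPM (mean ± SD, n = 3), at least 107-fold lower. Its call was lost in every fit without 1 library except that without GFP-positive library 3 (up to 0.0951 without GFP-negative library 1).

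Genes often listed for senescence moved in both directions. Of 10 measured cell-cycle inhibitors and related genes 1 was higher, 2 were lower and 7 did not pass, against 1 higher and 4 lower adjusted over the list alone (median −0.64; camera adjusted p = 0.366 with a preset correlation and 0.546 with an estimated correlation). Cdkn2a, with 49 counts in GFP-positive and 0 in GFP-negative libraries, is also in this list but was removed by the filter. Cdkn2d, the inhibitor p19Ink4d, fell by 2.54 ± 0.38 on the log2 scale (SE, n = 3 each; edgeR adjusted p = 0.00584). Rbl2, a pocket protein, was at −1.67 ± 0.40 (adjusted p = 0.0300) and Cdkn1c, the inhibitor p57, at 1.33 ± 0.34 (adjusted p = 0.0390). Both lost their call in every fit without 1 library except that without GFP-positive library 3 (up to 0.101 without GFP-negative library 1 and 0.123 without GFP-negative library 3). Of 22 senescence-associated secretory genes 6 were higher, 3 lower and 13 not past the test, against 7 higher and 4 lower adjusted over the list alone. The median was 1.04, and the camera adjusted p was 0.0409 with a preset correlation (adjusted p = 0.152 with an estimated correlation). Igfbp7, a secreted binding protein abundant in endothelium, stood at 2501 ± 239 against 906 ± 70.4 CPM, a log2 fold change of 1.47 ± 0.11 (adjusted p = 0.000300). Il1a, interleukin 1 alpha, rose by 2.40 ± 0.31 (adjusted p = 0.00332).

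Among the lower secretory genes, Plaur, the urokinase receptor, fell by 4.33 ± 0.29 (SE, n = 3 each; edgeR adjusted p = 0.000187). Tgfb1 was at −0.82 ± 0.18, a call lost without any 1 GFP-negative library or GFP-positive library 2 (up to 0.0874 without GFP-negative library 2). Tnf held 1 count over the GFP-positive group, with a GFP-negative to GFP-positive ratio of 393 (95% counting interval 70.6 to 15533). It lost its call in every fit except that without GFP-positive library 2 (up to 0.0881 without GFP-negative library 1). Its fitted log2 fold change was −8.19, or −10.18 without GFP-positive library 2. Among the higher ones, Il1b, at 4.49 ± 1.10, lost its call without GFP-negative library 2 (adjusted p = 0.108) or any 1 GFP-positive library (0.0598 to 0.0780), with a log2 fold change of 6.45 without GFP-negative library 3. Mmp12, at 3.77 ± 0.74, lost its call without GFP-negative library 1 (0.0686), with a log2 fold change of 4.38 without GFP-negative library 2. Of 13 proliferation genes 1 was higher and 12 not past the test, with 0 adjusted over the list alone, 2 at an unadjusted p under 0.05 and 2 past the test with DESeq2 (median 0.75; camera adjusted p = 0.202). It was Aurkb, a mitotic kinase, with 3 counts over the GFP-negative group and a GFP-positive to GFP-negative ratio of 113 (38.6 to 547). Its call was lost whichever library was left out (up to 0.156 without GFP-negative library 1), and its fitted log2 fold change was 6.75, or 9.64 without GFP-negative library 3. Without GFP-positive library 1, 1 of 16 measured proliferation genes was lower. Kupffer cell markers, with a median of 3.999, and B cell markers, with a median of −6.93, moved in the same libraries.

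Genes of the transition from endothelium to mesenchyme and of TGF-beta signalling, of Notch signalling, of mitochondria and of ribosomes showed few calls. Of 11 genes of the transition and TGF-beta list 1 was higher, 1 lower and 9 not past the test, against 2 higher and 2 lower adjusted over the list alone (median 0.77; camera adjusted p = 0.478). Without GFP-positive library 1, 2 of 12 measured members were higher, and without GFP-positive library 3, 2 of 11 were lower. Smad7, an inhibitor of TGF-beta signalling, fell by 1.99 ± 0.34 on the log2 scale (SE, n = 3 each; edgeR adjusted p = 0.0101). Zeb2, a transcription factor, was at 1.11 ± 0.31 (adjusted p = 0.0492). This call was lost in every fit without 1 library except that without GFP-positive library 1 (up to 0.146 without GFP-negative library 1), and with DESeq2's size factors or library totals alone (0.0506 and 0.0593). Of 8 Notch pathway genes 2 were lower and 6 not past the test, against 1 higher and 2 lower adjusted over the list alone, with a median of 0.55 and a mean of −1.05, which differ in sign (camera adjusted p = 0.892). Over the 10 members then measured, the median was 1.47 without GFP-negative library 3, and 1 was higher without GFP-positive library 3. Notch2, which mature B cells of the marginal zone depend on, held 1 count over the GFP-positive group against 93.1 ± 8.41 CPM in GFP-negative libraries, a GFP-negative to GFP-positive ratio of 4781 (95% counting interval 858 to 188827). Its fitted log2 fold change was −11.80, or −13.77 without GFP-positive library 3. Hes1, a target of Notch signalling, was at −1.14 ± 0.30 (adjusted p = 0.0408) and lost its call whichever library was left out (up to 0.141 without GFP-negative library 2).

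Of 12 mitochondrially encoded genes 0 passed with edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and 0 passed with DESeq2. Their median was 0.20 (camera adjusted p = 0.202 with a preset correlation and 0.739 with an estimated correlation). With the preset correlation the camera adjusted p was 0.0234 without GFP-negative library 2 and 0.0130 without GFP-positive library 3. In these fits 0 of the 31 lists passed with an estimated correlation. Over all libraries the estimated correlation of the mitochondrial list was 0.590, far above the preset 0.01. Mitochondrially encoded genes took 4.96 ± 0.706% of counts in GFP-negative and 5.35 ± 1.07% in GFP-positive libraries (mean ± SD, n = 3 each). Of 28 ribosomal protein genes 1 was lower, also adjusted over the list alone (median −0.14; camera adjusted p = 0.0685 with a preset correlation and 0.750 with an estimated correlation). It was Rpl4, at −0.63 ± 0.10 (SE; edgeR adjusted p = 0.00705). Without GFP-positive library 1, 3 were lower, and without GFP-positive library 3 the median was 0.048. With the preset correlation the list passed, downward, with library totals alone (0.0376), without a filter (0.0489), with the filter of 50 counts (0.0444) and without immunoglobulin, B, T and NK cell genes (0.0438). It also passed without GFP-negative library 3 (0.0182), GFP-positive library 1 (0.00133) or GFP-positive library 2 (0.0128). But the estimated correlation of the ribosomal list was 0.758, far above the preset 0.01. With an estimated correlation and library totals alone, its camera adjusted p was 0.714.

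By camera with its preset correlation 20 of the 31 lists passed, and with an estimated correlation 13 did. The 13 were the lists of Kupffer cell, macrophage and monocyte, sinusoidal, pan-endothelial, arterial, platelet and B cell markers and of scavenger receptor, lysosomal, antioxidant, interferon, lipid and immediate-early genes. Another 7 passed with the preset correlation alone. They were the lists of T and NK cell, erythroid, hepatocyte and stellate cell markers and of secretory, matrix and antigen presentation genes. With 1 library left out the preset correlation gave 20 or 21 lists. With an estimated correlation 10, 0 and 9 lists passed without GFP-negative library 1, 2 and 3, and 0, 6 and 0 without GFP-positive library 1, 2 and 3. In the 3 fits that gave 0 lists, 14, 16 and 13 had an unadjusted p under 0.05, and the highest adjusted p among the 13 was 0.0725, 0.0895 and 0.109.

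**Figure D2:**
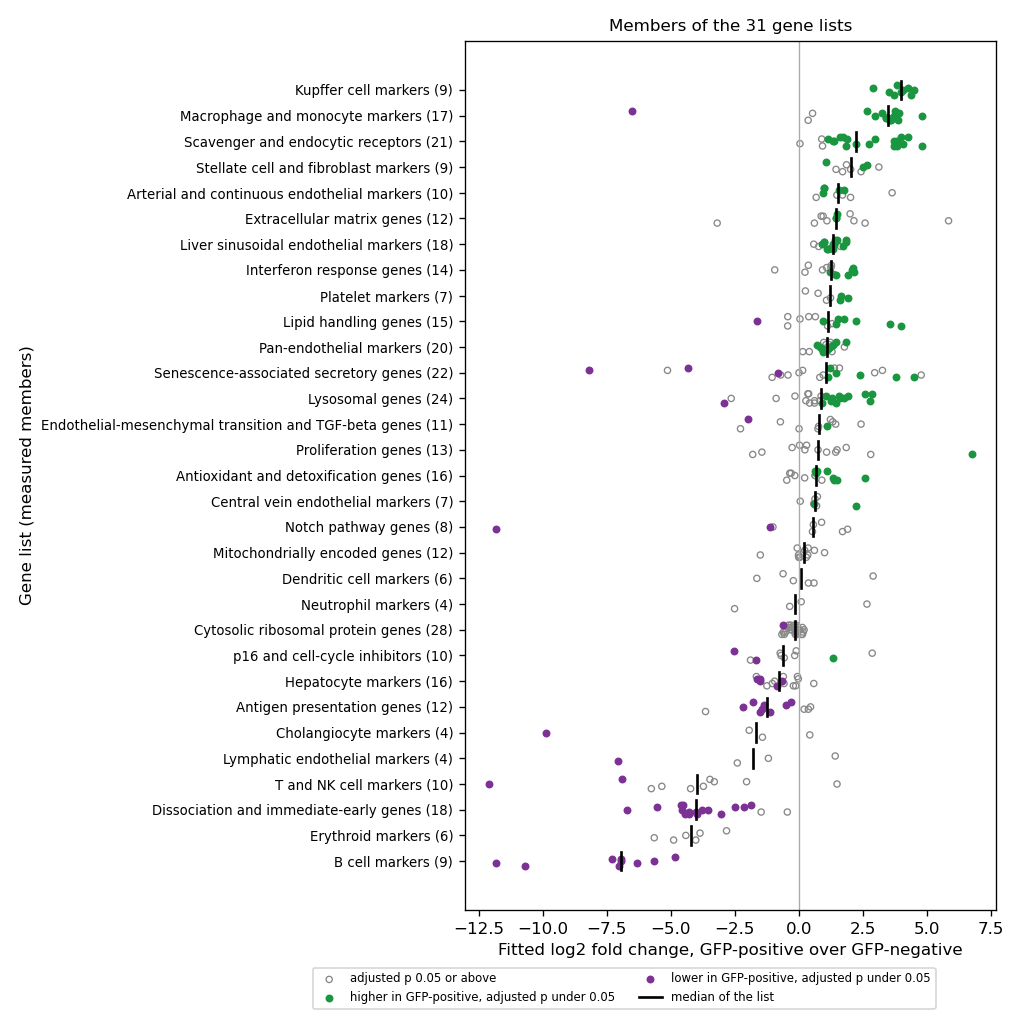
Log2 fold changes of the measured members of the 31 lists fixed before the data were examined, GFP-positive against GFP-negative (n = 3 each), with a point per gene, filled where the edgeR adjusted p was under 0.05, and a black bar at each median. The medians run from −6.93 for B cell markers to 3.999 for Kupffer cell markers.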

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

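The tests without immunoglobulin, B, T and NK cell genes, the filters applied to replicate similarity and the 6 added lists were chosen only after the results were seen. No paired analysis was possible because the labels give no animal or shared replicate number. Of the 2157 genes past the test, 2129 also passed with DESeq2's Wald test, all in the same direction, and DESeq2 called 3225 genes, of which 1426 were higher. An adjusted p under 0.01 left 754 genes, 342 higher and 412 lower, by its own construction. Leaving out 1 library left 920 to 1603 genes, 448 to 598 higher and 472 to 1005 lower, with fewer libraries in each fit. The other settings gave 1556 to 2648 genes. Higher genes made up 43.0% of the calls and 37.3% to 48.1% under the other scalings, which moved the median of all genes by under 0.1 on the log2 scale. Of the 31 lists, 20 passed with the preset correlation and 13 with an estimated one. By fry, which asks whether a list changed and not whether it differs from other genes, 22 passed. Other settings gave 19 to 21 with the preset correlation and 0 to 14 with an estimated one, over 29 to 31 lists. Of 111 genes chosen to be named and past the test, 81 kept the call whichever library was left out, 30 lost it at least once and 20 moved by over 1.5 times. No chosen gene or list reversed its direction past the test. The mean of Cdkn2a in GFP-positive libraries stayed between 0.660 and 1.25 CPM, and where it was tested its adjusted p was 0.0803 to 0.157. DESeq2's Wald test and voom gave no value for it, because the filter removes it. The lowest correlation within a group was 0.866, and 0.865 or 0.861 under other filters. In simulated data with far fewer changed genes, drawn from a middle range of mean counts, 2-fold changes were recovered for 4% of genes. A gene that did not pass is not shown to be equal.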

Other observations

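The tests of the 5 lists described first, of the Kupffer cell share and of captured molecules were chosen only after the results were seen. The splits with an estimated correlation were added after those with the preset one had been seen, and before their own result was. The list of early-response genes was added after the data had been seen, and its bounds were written before its own values were.

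Genes of iron handling and complement, which liver macrophages use to recycle red cells and clear particles, were higher in GFP-positive libraries. Of 9 iron handling genes 7 were higher, 1 was lower and 1 did not pass, with 7 and 1 adjusted over the list alone (median 1.93; camera adjusted p over the 6 added lists = 0.0157 with an estimated correlation, 0.0563 without GFP-negative library 3). Of these 9, 3 are also in other lists. Slc11a1, a metal transporter of phagosomes, stood at 286 ± 33.7 against 17.5 ± 5.31 CPM (mean ± SD, n = 3 each), a log2 fold change of 4.03 ± 0.29 (SE; edgeR adjusted p = 0.000272), and Ftl1, ferritin light chain, rose by 1.22 ± 0.10 (adjusted p = 0.000390). Fth1, ferritin heavy chain, was at 0.037 ± 0.11 (adjusted p = 0.871). The lower member was Tfrc, the transferrin receptor, with 3 counts over the GFP-positive group and a GFP-negative to GFP-positive ratio of 746 (95% counting interval 255 to 3619), and its log2 fold change was −9.36, or −12.70 without GFP-positive library 1. Of 11 complement genes 9 were higher and 2 not past the test, against 10 higher adjusted over the list alone (median 3.38; camera adjusted p = 0.0148 with an estimated correlation), and 3 of the 11 are also in other lists. Cfp, properdin, rose by 3.62 ± 0.22 (adjusted p = 0.000132) and C6, a component of the membrane attack complex, by 3.24 ± 0.24 (adjusted p = 0.000305). Of 8 Kupffer cell transcription factors 2 were higher, 1 lower and 5 not past the test, against 5 higher and 1 lower adjusted over the list alone (median 0.87; camera adjusted p = 0.118 with an estimated correlation). The higher members were Zeb2, named above, and Nr1h3. Nr1h3, the oxysterol receptor LXR alpha, was at 3.56 ± 0.74 (adjusted p = 0.0198, and 0.0825 without GFP-negative library 2; 4.20 without GFP-negative library 3), and Irf8 fell by 1.31 ± 0.23 (adjusted p = 0.0107). Kupffer cell markers, 9 of 9 higher with a median of 3.999, rose in the same libraries.

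Genes of naive and follicular B cells were lower in GFP-positive libraries. Of 7 naive B cell and germinal centre genes 6 were lower and 1 not past the test, with 7 lower adjusted over the list alone (median −6.34; camera adjusted p = 0.0157 with an estimated correlation). Ccr7, a homing receptor of lymph nodes, stood at 27.3 ± 6.85 against 3359 ± 294 CPM (mean ± SD, n = 3 each), a log2 fold change of −6.94 ± 0.25 (SE; edgeR adjusted p = 1.7e-05), and Fcer2a, the low-affinity IgE receptor of B cells, fell by 6.34 ± 0.43 (adjusted p = 0.000188). Of 6 plasma cell genes 2 were lower and 4 not past the test, with 2 adjusted over the list alone (median −3.67; camera adjusted p = 0.193 with a preset correlation and 0.269 with an estimated correlation). The lower members were Mzb1, at −5.36 ± 0.95 (adjusted p = 0.0114), and Prdm1. Prdm1 held 1 count over the GFP-positive group, with a ratio of 249 (95% counting interval 44.8 to 9848), and its call (adjusted p = 0.0274) was lost whichever library was left out, up to 0.0958 without GFP-negative library 1. Its fitted log2 fold change was −7.54, or −9.52 without GFP-positive library 2. Jchain, the joining chain of secreted antibodies, was at 2.40 ± 2.54 and Xbp1 at 0.28 ± 0.16 on the log2 scale, neither past the test (adjusted p = 0.601 and 0.295). Jchain was at 8.89 without GFP-negative library 1 and at 1.75 without GFP-positive library 2. Whether the 2 B cell lists differ was not tested.

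The lower level of immediate-early and heat-shock genes was weighed against the lymphocyte transcripts of the GFP-negative libraries and against stress during cell handling. Early-response genes that lymphocytes hardly use were compared with the pan-endothelial markers in each library, and that difference between the groups was −0.083 ± 0.68 on the log2 scale (SE, n = 3 each, 4 of 8 listed genes measured). Of these 4 genes, with a median of 0.77 (camera adjusted p = 0.206 with a preset correlation and 0.269 with an estimated correlation), Adamts1 alone passed, upward, at 1.83 ± 0.48 (edgeR adjusted p = 0.0405, lost without any 1 library but GFP-negative library 3, up to 0.128 without GFP-negative library 2). Without GFP-positive library 3 or GFP-negative library 3 the filter kept 5 of the 8, with medians of −0.33 and 1.98, so the genes differ too. The difference of −0.083 lay within the bound set for lymphocyte RNA. It lay outside that set for stronger handling stress in GFP-negative cells of every type. But the libraries of the groups overlapped, and 4 genes with that error, of which Ccn1 and Ccn2 are low, cannot tell these explanations apart. No conclusion on either is drawn. Stress in lymphocytes alone, the reporter state itself and a culture step stay open and untested.

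Kupffer cell markers in cells selected for CD31 were weighed against a lower share of lymphocytes in the GFP-positive fraction, which would raise the markers of every other cell alike. The mean of the Kupffer cell markers less that of the pan-endothelial markers was higher in GFP-positive libraries by 2.86 ± 0.0859 on the log2 scale (SE, n = 3 each), and the mean of the hepatocyte markers changed by −0.75 ± 0.153, so a lower lymphocyte share alone does not account for the rise. The most abundant of these transcripts was Clec4f, at 5212 CPM, and the magnetic CD31 selection is meant to remove cells without CD31. Why GFP-positive libraries held more Kupffer cell transcripts remains open and untested. Shares of RNA do not count cells, so more Kupffer cells in the GFP gate are not shown. Use of the p16 promoter may have been more frequent among Kupffer cells, as the design would allow. Their autofluorescence, or endothelial fragments that they carried, are other candidates. Binding to beads came before the sort and would bring Kupffer cells into both fractions, so it does not by itself give this difference.

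In each group some genes stood at 0 or 1 count in 1 library and over 100 counts in the other 2. There were 594 such genes, 53 to 165 per library. The largest share in 1 library was 27.8%, which argues against 1 poor library as the only source. That share was in GFP-positive library 2, with 165 genes against 119 and 105 in GFP-positive libraries 1 and 3. GFP-positive library 2 was also set apart on a principal component, at −136.7. Among 2343 entries of a gene and group with a mean of 50 to 100 counts, 19.1% of library values were 0 or 1, in GFP-negative (15.96%) as in GFP-positive (22.1%) libraries. Such values may come from few captured RNA molecules that were each read many times, although the labels' protocols state an input of 1 μg of RNA, and they would widen the spread of weakly expressed genes, Cdkn2a among them. How many cells were sorted is not given in the sources used here.

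The 6 libraries can be parted into 3 and 3 in 10 ways, which is too few for a share under 0.05. For genes past edgeR's test, 1 of the 10 splits gave as many as the real one, the real one itself, with 2157 genes against a highest other of 0, while the other splits held 129 to 182 genes at an unadjusted p under 0.05 and 21 to 37 by DESeq2. For lists with an estimated correlation it was also 1 of 10, with 13 lists against a highest other of 0, and at most 2 at an unadjusted p under 0.05. For lists with the preset correlation, 2 of the 10 splits gave as many, with 20 lists in the real split and 22 in the highest other, which joined GFP-negative libraries 1 and 3 with GFP-positive library 1. Every other split sets 2 libraries of 1 group and 1 of the other against the rest. Part of the real difference thus stays in such a split, and the remainder widens its spread. The other splits therefore do not show what libraries without a difference would give. No conclusion on chance is drawn from these counts of genes and lists.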
